A study of Homo sapiens with 34 samples.

How the data were processed

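Total RNA was taken from fresh frozen hepatocellular carcinoma and paired non-neoplastic liver of 17 patients on an automated extraction instrument, and libraries were made with a stranded total RNA kit, per the labels' protocols. The deposited table holds 1 column of estimated counts per library and 35423 lines named by gene symbol. The values are whole numbers that sum to different totals. Salmon 0.99.0, a quantifier that assigns reads to transcripts, DESeq2, FastQC and the builds GRCh38 and hg38 are named in the submitters' processing notes, without a role for each. How transcript estimates became whole numbers per gene, and which annotation was used, is not given in the sources used here. The deposited values were treated like expected counts and passed through rounding to whole numbers. Such a quantifier divides reads that fit several near-identical genes by estimation, so values of paralogs are less certain.

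Each column was matched to its sample by the title in the labels, and tissue and patient were taken from the labels. A total of 27 lines carry a calendar date in place of a gene symbol (25 different names, 0.132% of the counts) and were left out. A further 347 sex-linked lines were left out, though X-linked genes such as GPC3 were kept, which leaves 35049 lines. GENCODE release 29 on GRCh38 gave positions and gene types for 27806 of these, and RefSeq symbols and synonyms matched 27402. Genes were filtered with filterByExpr, which kept 16479, and libraries were scaled by TMM factors. Carcinoma was compared with non-neoplastic tissue in edgeR 4.0.16 (glmQLFit, glmQLFTest; R 4.3.3) with the patient as a block, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The standard error of a log2 fold change is its absolute value over the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over the 17 libraries of a tissue, and the prior count for log2 CPM was 2.

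The pairing comes from the labels, which give each patient 1 sample of each tissue. Over tested genes, the deviations from the tissue means correlated at 0.085 on average between the 2 samples of a patient and at -0.0046 between samples of different patients (permutation of the matching, p = 0.017), with 10 of the 17 pairs over 0.1.

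A total of 37 gene lists were written from textbook knowledge, of which 35 had at least 5 tested members. Lists were tested with camera from limma 3.58.1 with the preset correlation of 0.01, and with the correlation estimated for each list and with fry as alternatives. Of the 21 lists called with the preset correlation, 0 were called with the estimated one. Fry tests whether the genes of a list move, on balance, in a common direction and does not compare them with other genes. A list score is the mean log2 CPM of its tested members. The spread between patients, the make-up of libraries and the scores of lists and chromosome arms were tested by 100000 swaps of the tissue labels within patients, two-sided, for which the smallest p is 1e-05. Chromosomes were split into arms at the widest gap between genes, acrocentric chromosomes were kept whole, and sex chromosomes were left out. On chromosome 4 that gap (31146806 to 35487811) lies within the short arm, so the sets labelled 4p and 4q are not whole arms. Arms were tested with camera with an estimated correlation.

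The design, the tests, the gene lists, the first set of alternative settings and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 1, an approved symbol, no pseudogene and the same direction in at least 15 pairs, a fixed panel of markers, and, for each list, the 3 members with the smallest p in the direction of most called members and the 1 with the smallest p in the other. Some genes that the rule names are not reported here.

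On simulated counts for the same comparison, with 16201 genes in the step, 84.8% and 78.0% of the genes changed by -2 and 2 on the log2 scale were called, 30.4% and 24.0% of those changed by -1 and 1, and 0 of 16009 unchanged genes. Camera called the simulated changed list (adjusted p = 2.90e-31) and 0 of 40 unchanged ones. Genes were drawn independently there, while the estimated correlation in the data was, for example, 0.63 for the mitosis list. How often camera calls unchanged lists of correlated genes was therefore not shown. For a simulated log2 SD ratio of 0.58 over 16479 genes the spread test returned 0.59. Tested on simulated data with 5q raised by 0.5, the arm test called that arm and 0 of 38 others. Genes were independent there too, while the estimated correlation in the data was 0.12 for 8q. Whether a shift of 0.5 would be called at such a correlation was not simulated. The shallowest library held 5360664 counts, so low genes are measured with less precision there.

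Alternatives were DESeq2 1.42.0 and limma-voom with the patient term, edgeR without the patient block, RLE and upper-quartile factors, no filter, a stricter filter, other thresholds, and leaving out the mitochondrially encoded genes or each patient in turn. Chosen after seeing the data were total counts as a covariate, thinning of all libraries to the smallest total, leaving out the 3 pairs with the shallowest libraries or libraries far from their own tissue, and the permutation of list and arm scores.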

Results

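RNA was sequenced from fresh frozen hepatocellular carcinoma, the main primary cancer of the liver, and from non-neoplastic liver of the same patients. Each of 17 patients gave 1 carcinoma and 1 non-neoplastic sample, so the 34 libraries form 17 pairs. The carcinoma libraries held 17017411 to 55552204 estimated counts (median 23911048) and the non-neoplastic libraries 5360664 to 37878535 (median 14950112). In 15 of the 17 pairs the carcinoma library was the deeper one. The question the design states is which genes differ between the carcinoma and the non-neoplastic tissue of a pair.

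Markers of sinusoidal endothelium, the specialised lining of liver capillaries, and of resident liver macrophages were among the largest decreases in carcinoma. The oncofetal proteoglycan gene GPC3, cell cycle genes and histone genes were among the largest increases. STAB2, a scavenger receptor of sinusoidal endothelium, fell from 156.4 ± 124.3 CPM (counts scaled by library size; mean ± SD, n = 17) in non-neoplastic tissue to 14.4 ± 43.4 CPM in carcinoma, with a fitted log2 fold change of -8.22 ± 1.13 (SE). MARCO, a scavenger receptor of Kupffer cells, went from 36.2 ± 35.1 to 4.02 ± 11.9 CPM (log2 fold change -7.08 ± 0.95). Of the carcinoma counts, 1 library held 3610 of 5408 for STAB2 and 1 held 974 of 1524 for MARCO. The carcinoma means rest largely on few libraries, so the means differ by less than the fitted folds. GPC3 went the other way, from 12.7 ± 39.7 to 157.7 ± 215.6 CPM (log2 fold change 4.87 ± 0.91), and was higher in 15 of the 17 pairs. Of the non-neoplastic counts of GPC3, 1 library held 5432 of 6344, so its non-neoplastic mean rests largely on that library.

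In all, 3138 of 16479 tested genes were higher and 3272 lower in carcinoma by edgeR's quasi-likelihood test with the patient as a block, at a Benjamini-Hochberg adjusted p below 0.05. The decreases were larger than the increases: the median absolute log2 fold change was 1.40 for the lower and 0.92 for the higher genes, and 280 genes were lower by 8-fold or more against 20 that were higher by as much. Of the 6410 called genes, 2651 moved the same way in at least 15 of the 17 pairs. Of the 34 libraries 4 lay nearer to the other tissue than to their own, 3 of them non-neoplastic: both libraries of 1 pair and 1 library in each of 2 further pairs. Without the pair in which both did, 3986 genes were higher and 3647 lower. Total counts differed with tissue, and with log2 total counts added to the edgeR model beside the patient, 75 genes were called higher and 318 lower. Both of these alternatives were chosen after seeing the data. Depth and tissue cannot be fully separated in this design. A call lost in the model with total counts therefore does not show that depth caused the difference.

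The 10 largest decreases among genes that moved the same way in at least 15 pairs were STAB2, CLEC1B, GDF2, DBH, MUC5B, CLEC4G, MUC6, MARCO, CLEC4M and CDHR2. CLEC4M and CLEC4G, lectin genes of sinusoidal endothelium that lie close together on chromosome 19 (GRCh38, 7763149 to 7769605 and 7728957 to 7733906), had log2 fold changes of -7.00 ± 0.91 and -7.42 ± 1.15. CLEC1B, at 9985642 to 10013424 on chromosome 12, went from 8.03 ± 6.00 to 1.27 ± 3.84 CPM (log2 fold change -7.84 ± 1.13), and GDF2, which encodes the circulating ligand BMP9, had a log2 fold change of -7.71 ± 1.05. DBH, the enzyme that makes noradrenaline, fell as well (log2 fold change -7.54 ± 0.97). The mucin gene MUC5B fell from 21.8 ± 48.5 to 0.29 ± 0.94 CPM. The number of carcinoma libraries at 0 counts was 12 for CLEC1B, 11 for GDF2, 11 for DBH, 8 for CLEC4G and 9 for MUC5B. The size of these fitted folds thus rests partly on libraries in which no count was assigned. For CLEC1B 1 carcinoma library held 310 of the 479 carcinoma counts. The edgeR adjusted p of these 10 genes lay between 0.00014 for MUC5B and 0.00042 for MUC6, and each was lower in 15 or 16 of the 17 pairs. With log2 total counts in the model STAB2, MUC5B, CLEC4M and CDHR2 were still called (edgeR adjusted p of 0.035 to 0.047). CLEC1B, GDF2, DBH, CLEC4G, MUC6 and MARCO were not (adjusted p of 0.051 to 0.13). Their log2 fold changes were then between -5.74 for CLEC4G and -5.01 for MARCO.

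The 10 largest increases by the same rule were GPC3, PIGT, SLC33A1, TGM3, SPIN3, H2BFS, ACSM1, ASPM, CDC20 and HIST1H3B. ASPM, a spindle pole gene at 197084128 to 197146694 on chromosome 1, rose from 9.32 ± 8.56 to 66.3 ± 55.7 CPM in 15 of 17 pairs (log2 fold change 2.78 ± 0.48, edgeR adjusted p = 0.00048). ACSM1, a mitochondrial acyl-CoA synthetase gene, rose from 3.79 ± 2.77 to 50.7 ± 89.2 CPM (log2 fold change 2.93 ± 0.54). The transglutaminase gene TGM3 rose, with a log2 fold change of 3.38 ± 0.91. PIGT had 0 counts in 6 of the non-neoplastic libraries, SPIN3 in 10 and H2BFS in 7, so their log2 fold changes of 4.86 ± 0.84, 3.32 ± 0.88 and 3.07 ± 0.80 rest partly on libraries in which no count was assigned. H2BFS and HIST1H3B belong to a family of near-identical histone genes, among which the assignment of reads is uncertain. Of the 10 genes, only ACSM1 was called with log2 total counts in the model (log2 fold change 3.49, edgeR adjusted p = 0.043). H2BFS, HIST1H3B and CDC20 were then at 0.75, 0.95 and 1.21 (adjusted p = 0.61, 0.44 and 0.40), against 3.07, 2.54 and 2.75. GPC3, PIGT, SLC33A1, TGM3, SPIN3 and ASPM were at 3.49, 2.535, 2.27, 4.11, 1.98 and 2.08 (adjusted p of 0.077 to 0.30).

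Among genes widely used to describe hepatocellular carcinoma, CAP2 rose from 6.89 ± 5.50 to 39.0 ± 34.4 CPM (log2 fold change 2.30 ± 0.42, edgeR adjusted p = 0.00060, higher in 16 of 17 pairs). The aldo-keto reductase gene AKR1B10 had a log2 fold change of 3.78 ± 1.03 and was higher in 13 pairs, and the trypsin inhibitor gene SPINK1 had a log2 fold change of 4.55 ± 1.42 and was higher in 12. The model with log2 total counts called none of CAP2, AKR1B10 and SPINK1, with log2 fold changes of 2.12, 4.13 and 0.25 (adjusted p = 0.063, 0.16 and 0.95). GLUL, glutamine synthetase, rose from 526.3 ± 241.6 to 3456 ± 5644 CPM, with a fitted log2 fold change of 1.33 ± 0.50 (edgeR adjusted p = 0.040, higher in 12 pairs). IGF2, a growth factor gene, fell in all 17 pairs, from 1656 ± 1408 to 156.2 ± 270.3 CPM (log2 fold change -4.86 ± 0.72, edgeR adjusted p = 0.00024). HAMP, which encodes the iron hormone hepcidin, fell in 16 pairs (log2 fold change -4.98 ± 0.79). AFP at 0.21 ± 0.49, CD34 at 0.39 ± 0.23 and CYP1A2 at -3.11 ± 1.41 (log2 fold change) did not pass the edgeR test, with adjusted p of 0.75, 0.18 and 0.084. Without the pair nearer to the other tissue CD34 (0.58, adjusted p = 0.026) and CYP1A2 (-3.51, adjusted p = 0.026) did pass. TERT, at 0 counts in 10 carcinoma and 12 non-neoplastic libraries, was below the count filter and was not tested. Its counts summed to 454 in carcinoma, of which 1 library held 322, and to 9 in non-neoplastic tissue. H19 was not analysed here.

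**Figure D1:**
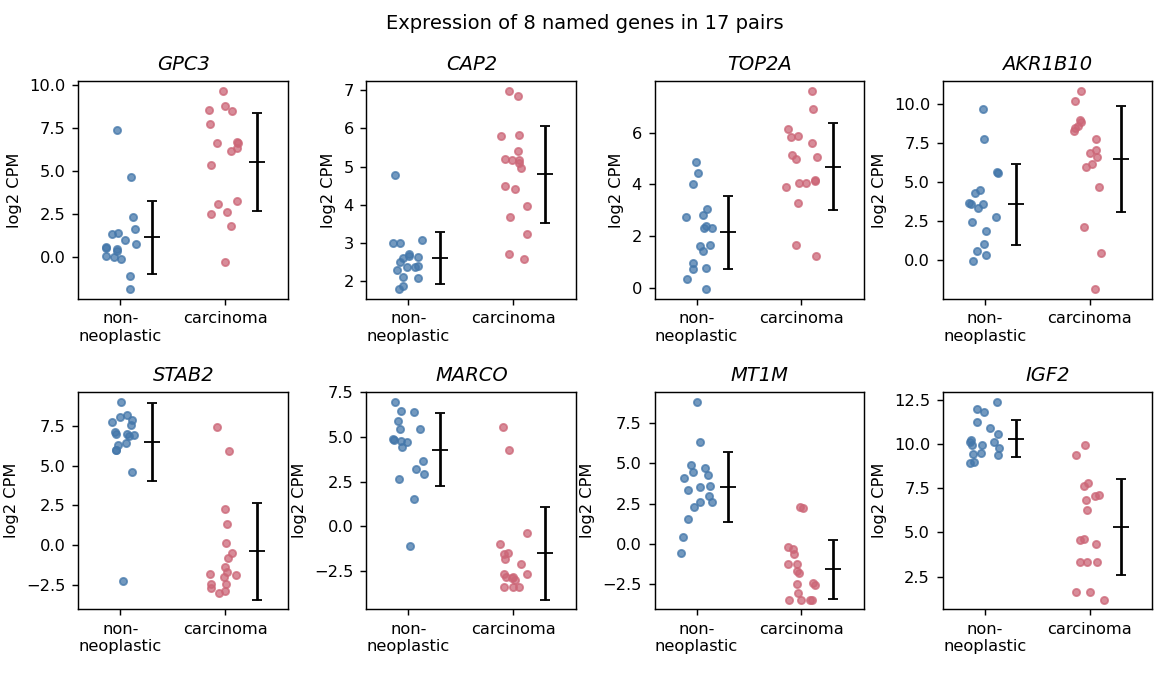
Each panel shows the log2 CPM of 1 gene in the 17 non-neoplastic (blue) and 17 carcinoma (red) libraries, with a point per library and, beside the points, a bar of the mean with the SD. GPC3, CAP2, TOP2A and AKR1B10 lie higher in carcinoma and STAB2, MARCO, MT1M and IGF2 lower, with log2 fold changes from -8.22 for STAB2 to 4.87 for GPC3.

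Most of the listed cell division genes rose in carcinoma. Of 24 mitosis genes 20 rose and 0 fell, with a median log2 fold change of 1.85. AURKA, the Aurora A kinase gene, was higher in 17 of 17 pairs (2.16 ± 1.45 to 14.3 ± 13.1 CPM, log2 fold change 2.43 ± 0.35) and TOP2A, which untangles DNA, in 16 (log2 fold change 2.52 ± 0.55). Of 24 DNA replication genes 17 rose and 0 fell, among them PCNA, the sliding clamp of DNA polymerase (log2 fold change 1.61 ± 0.29), FEN1 (1.70 ± 0.39) and MCM3 (1.22 ± 0.27). Of 21 replication-dependent histone genes 18 rose and 0 fell, HIST1H1C from 22.1 ± 21.3 to 74.5 ± 58.0 CPM (log2 fold change 1.98 ± 0.29). Adjusted over the list alone, 20, 18 and 18 genes rose in the 3 lists and 1 mitosis gene fell. Camera with its preset correlation called the mitosis, replication and histone lists higher, with Benjamini-Hochberg adjusted p of 1.16e-08, 1.37e-06 and 2.99e-07. The adjusted p was 0.30 for each with an estimated correlation. The mean score of the list was higher in 15, 14 and 16 of the 17 pairs. With log2 total counts in the model 1, 0 and 1 genes of the 3 lists rose and 0 fell, with median log2 fold changes of 0.98, 0.72 and 0.70.

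Most listed nuclear genes of the respiratory chain rose in carcinoma while most transcripts of the mitochondrial genome fell. Of 27 nuclear oxidative phosphorylation genes 21 rose and 0 fell (23 and 0 adjusted over the list alone), among them NDUFA1 (13.9 ± 12.6 to 37.1 ± 16.8 CPM, log2 fold change 1.78 ± 0.28) and COX6C (1.76 ± 0.30). Of the 13 mitochondrially encoded genes 11 fell and 0 rose (13 and 0 adjusted over the list alone), MT-ND1 from 3473 ± 2860 to 775.8 ± 510.2 CPM (log2 fold change -1.88 ± 0.49) and MT-ND6 with a log2 fold change of -2.53 ± 0.65. Of 25 proteasome and chaperone genes 22 rose and 0 fell, also adjusted over the list alone, among them PSMB5 (log2 fold change 1.43 ± 0.25), PSMB4 (1.41 ± 0.25) and the chaperone gene HSPA4 (1.17 ± 0.22). Of 25 splicing genes 10 rose and 2 fell, also adjusted over the list alone, with SNRPB at 1.48 ± 0.31 and SNRPD2 at 1.47 ± 0.30 against SFPQ at -0.67 ± 0.22 (log2 fold change). The preset adjusted p of camera was 1.16e-08, 3.22e-05, 1.01e-08 and 0.0056 for the 4 lists, and the adjusted p was 0.30, 0.38, 0.30 and 0.41 with an estimated correlation. With log2 total counts in the model 0 genes of these 4 lists rose or fell. The median log2 fold changes were then 0.31, -0.71, 0.28 and 0.04, against 0.85, -1.67, 0.97 and 0.35 without total counts, and the preset camera adjusted p was 7.8e-05, 0.037, 0.0023 and 0.25.

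By Pearson's r the scores of the nuclear respiratory, proteasome and splicing lists also followed log2 total counts within each tissue. For nuclear oxidative phosphorylation Pearson's r was 0.86 over the 17 carcinoma libraries (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 7e-05) and 0.68 over the 17 non-neoplastic ones (p = 0.0025, adjusted p = 0.0059), with Spearman's rho of 0.87 (permutation p = 2e-05) and 0.65 (p = 0.0057). For the proteasome list r was 0.82 (permutation p = 4e-05, adjusted p = 0.00018) and 0.74 (p = 0.00071, adjusted p = 0.0020), with rho of 0.74 (p = 0.0012) and 0.58 (p = 0.016). For splicing r was 0.64 (permutation p = 0.0065, adjusted p = 0.011) and 0.66 (p = 0.0037, adjusted p = 0.0074), with rho of 0.75 (p = 0.0010) and 0.51 (p = 0.039), the last of which did not pass after adjustment (adjusted p = 0.061). Without the 2 libraries farthest from the median total, r was 0.81 and 0.75, 0.72 and 0.68, and 0.58 and 0.53. The mitosis score (r = 0.26 in carcinoma and -0.11 in non-neoplastic tissue, permutation p = 0.32 and 0.68, adjusted p = 0.44 and 0.68, rho 0.34 and -0.047 with p = 0.18 and 0.86) and the sinusoidal endothelium score (r = -0.13 and -0.24, permutation p = 0.63 and 0.34, adjusted p = 0.68 and 0.44, rho -0.16 and -0.15 with p = 0.53 and 0.56) did not pass this test. Without the same 2 libraries their r was 0.16 and 0.037, and -0.075 and -0.30. The first principal component followed total counts as well (r = 0.90 in carcinoma and 0.82 in non-neoplastic tissue, permutation p = 1e-05 and 5e-05, adjusted p = 7e-05 and 0.00018, rho 0.82 and 0.73 with p = 0.0001 and 0.0013). For the share of counts in the 13 mitochondrially encoded genes r was -0.12 and -0.48 (permutation p = 0.64 and 0.048, adjusted p = 0.68 and 0.074), with rho of -0.12 (p = 0.63) and -0.61 (p = 0.010, adjusted p = 0.020). Without the 2 libraries farthest from the median total the r of this share was 0.027 and -0.67. Other lists had an r above 0.4 in both tissues and were not tested, such as cholesterol synthesis (0.52 in carcinoma and 0.63 in non-neoplastic tissue), fatty acid oxidation (0.52 and 0.53), histones (0.44 and 0.68) and plasma proteins (0.43 and 0.70). The adjustment is over 14 such relations, which were chosen after seeing the data.

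**Figure D2:**
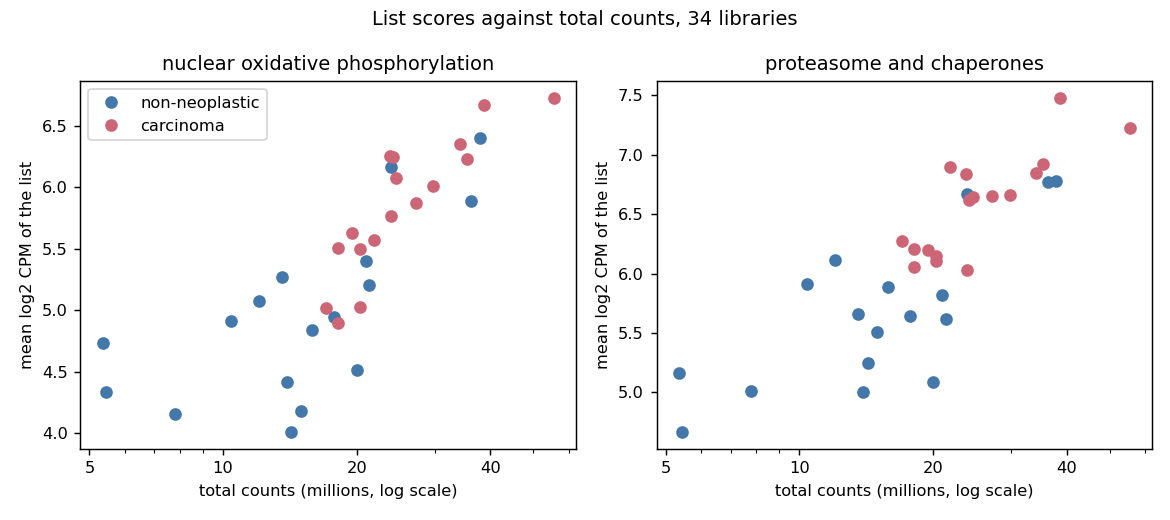
Each point is 1 of the 34 libraries (17 per tissue), with total counts on a log scale against the mean log2 CPM of a list's members. Both the nuclear oxidative phosphorylation score (r = 0.86 in carcinoma and 0.68 in non-neoplastic tissue) and the proteasome and chaperone score (r = 0.82 and 0.74) rise with total counts within each tissue.

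Part of the genes of the antioxidant NRF2 programme and of cholesterol synthesis rose. Of 18 NRF2 targets 9 rose and 0 fell, also adjusted over the list alone: AKR1C3 from 45.9 ± 76.4 to 159.1 ± 107.3 CPM (log2 fold change 2.35 ± 0.33), SRXN1, which restores peroxiredoxins (2.01 ± 0.36), and TXNRD1, thioredoxin reductase (1.70 ± 0.35), among them. Of 22 cholesterol synthesis genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), among them the epoxidase SQLE (log2 fold change 2.01 ± 0.41), PMVK (1.43 ± 0.24) and CYP51A1 (1.39 ± 0.33). The preset adjusted p of camera was 0.00021 for the NRF2 and 0.00026 for the cholesterol list, and the adjusted p was 0.30 and 0.38 with an estimated correlation. With log2 total counts in the model 1 NRF2 gene rose and 1 fell, and 0 cholesterol genes passed. The preset camera adjusted p was then 0.051 for the NRF2 and 0.0066 for the cholesterol list. The median log2 fold changes were 0.53 and 0.48, against 0.94 and 0.82 without total counts.

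Markers of the cells that line and support the liver sinusoid fell in carcinoma, while 6 of 18 genes of capillary and angiogenic endothelium rose. Of 15 sinusoidal endothelium genes 13 fell and 1 rose, also adjusted over the list alone, with a median log2 fold change of -4.01. The gene that rose was the fatty acid transporter CD36 (26.4 ± 16.6 to 84.4 ± 80.6 CPM, log2 fold change 1.26 ± 0.41), which other cell types express too. Of 15 stellate cell genes 13 fell and 1 rose, likewise adjusted over the list alone: PTH1R had a log2 fold change of -4.56 ± 0.65 and HHIP, an inhibitor of hedgehog signalling, of -3.99 ± 0.57, against 1.69 ± 0.51 for RGS5, which is also a pericyte gene. Of 18 capillary endothelium genes 6 rose and 1 fell, likewise adjusted over the list alone: the diaphragm gene PLVAP rose from 10.9 ± 15.3 to 42.3 ± 24.4 CPM (log2 fold change 2.69 ± 0.59), and ESM1 (3.46 ± 0.96) and COL15A1 (2.56 ± 0.72) rose as well, while TIE1 fell (-0.49 ± 0.18). Without the pair nearer to the other tissue 10 capillary genes rose and 0 fell. The preset adjusted p of camera was 2.84e-08, 9.14e-08 and 0.030, and the adjusted p was 0.30, 0.30 and 0.58 with an estimated correlation. The sinusoidal and stellate scores were higher in 1 of the 17 pairs each, and the capillary score in 13. With log2 total counts in the model 3 sinusoidal, 2 stellate and 0 capillary genes fell and 0 rose. The median log2 fold changes were then -2.49, -2.48 and 0.05, against -4.01, -2.71 and 0.61 without total counts, and the camera adjusted p of the capillary list was 0.86.

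Part of the listed immune and bile duct genes fell in carcinoma. Of 17 Kupffer cell and macrophage genes 7 fell, among them LILRB5 (65.5 ± 28.4 to 18.9 ± 18.1 CPM, log2 fold change -2.30 ± 0.37) and TIMD4 (-4.09 ± 0.70). Of 18 T and NK cell genes 10 fell, including the chemokine gene CCL5 (113.9 ± 52.8 to 41.2 ± 24.2 CPM, log2 fold change -1.56 ± 0.28), TIGIT (-1.90 ± 0.45) and CD8B (-2.23 ± 0.54). Of 10 B and plasma cell genes 9 fell, among them MS4A1, which encodes CD20 (log2 fold change -3.18 ± 0.56). Of 12 neutrophil and monocyte genes 9 fell, CSF3R (log2 fold change -2.42 ± 0.36) and FCN1 among them. Of 13 cholangiocyte genes 7 fell, among them KRT19 in 15 of 17 pairs (log2 fold change -6.26 ± 1.16) and PKHD1 in 15 (-3.58 ± 0.72). KRT19 was at 0 counts in 11 carcinoma libraries. Another carcinoma library held 618 of the 663 carcinoma counts of KRT19, above the highest non-neoplastic count of 419. In these 5 lists 0 members rose, and adjusted over the list alone 7, 13, 9, 11 and 7 fell and 0 rose. Camera with the preset correlation gave adjusted p of 0.0019, 0.00057, 3.22e-05, 3.22e-05 and 0.0019 in the same order, and the adjusted p was 0.34, 0.33, 0.30, 0.30 and 0.38 with an estimated correlation. In the same order 0, 0, 1, 4 and 1 genes fell with log2 total counts in the model, while the median log2 fold changes were -1.09, -1.24, -3.15, -2.04 and -2.89, against -0.55, -1.24, -3.28, -1.82 and -3.01 without them. With every library thinned to the smallest total the camera adjusted p of the cholangiocyte list was 0.064.

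Metallothioneins, small proteins that bind zinc and copper, fell together: all 8 tested genes were called lower, also adjusted over the list alone, with a median log2 fold change of -4.17. MT1M and MT1F fell in 17 of 17 pairs, MT1F from 65.6 ± 167.1 to 2.88 ± 7.77 CPM (log2 fold change -4.52 ± 0.63), while MT1M had a log2 fold change of -5.73 ± 0.79 and MT1H of -6.40 ± 0.85. These genes lie together on chromosome 16, MT1M at 56632233 to 56633986 (GRCh38), and resemble each other closely, so reads can be shared among them. For MT1F 1 non-neoplastic library held 23129 of the 30728 non-neoplastic counts, so its mean in that tissue rests largely on 1 library. Of 20 immediate early genes, which respond rapidly to stress and growth signals, 14 fell and 0 rose: FOSB went from 170.6 ± 211.6 to 18.0 ± 32.4 CPM (log2 fold change -4.04 ± 0.71), and EGR3 (-2.64 ± 0.45) and EGR2 (-2.31 ± 0.51) fell too. Of 18 chemokine and cytokine genes 11 fell and 0 rose, among them CXCL14 (log2 fold change -6.30 ± 0.99), CCL4 (-2.14 ± 0.36) and IL1B (-2.84 ± 0.58). CXCL14 was at 0 counts in 8 carcinoma libraries and MT1H in 5. Of 16 cytochrome P450 genes in the list named for drug metabolism 6 fell and 0 rose (10 and 0 without the pair nearer to the other tissue). Among those that fell were CYP2B6 (1967 ± 1161 to 408.8 ± 488.1 CPM, log2 fold change -3.17 ± 0.78), CYP26A1 (-3.23 ± 0.79) and CYP3A43 (-2.64 ± 0.75). Adjusted over the list alone, 14 immediate early, 11 chemokine and 7 cytochrome genes fell. By camera with the preset correlation the adjusted p was 4.31e-08, 5.46e-06, 6.77e-05 and 0.00057 for the metallothionein, immediate early, chemokine and cytochrome lists, and the adjusted p was 0.30, 0.30, 0.30 and 0.40 with an estimated correlation. With log2 total counts in the model 4, 1, 2 and 0 genes fell in the same order. The median log2 fold changes were then -4.14, -1.26, -2.18 and -0.61, against -4.17, -1.32, -1.82 and -1.77 without total counts, and the camera adjusted p of the cytochrome list was 0.053.

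Genes of the liver's own synthetic and metabolic lists were mostly not called. Of 23 hepatocyte plasma protein genes 0 passed the test, with log2 fold changes such as 0.73 ± 0.29 for AMBP and 1.23 ± 0.58 for SERPINC1; AMBP did pass without the pair nearer to the other tissue (adjusted p = 0.027). Of 24 urea cycle and amino acid breakdown genes 1 fell (UROC1, log2 fold change -3.45 ± 1.12), or 2 without the pair nearer to the other tissue. Of 21 acute phase and complement genes 1 fell (HAMP). Of 19 bile acid genes 5 rose and 0 fell, or 6 and 1 without the pair nearer to the other tissue. CYP7A1, the rate-limiting enzyme of bile acid synthesis, rose from 16.3 ± 24.8 to 209.2 ± 277.1 CPM (log2 fold change 3.45 ± 0.84). BAAT (1.30 ± 0.34) and AMACR (1.54 ± 0.39) rose as well. Of 20 glycolysis genes 5 rose and 5 fell, with PGAM1 (log2 fold change 1.26 ± 0.30), TPI1 (1.14 ± 0.28) and PGK1 (0.68 ± 0.19) higher and the neuronal enolase ENO2 (-2.46 ± 0.42) lower. Of 21 hepatocyte transcription factors 4 rose and 2 fell (7 and 2 without the pair nearer to the other tissue), CEBPA (log2 fold change 2.04 ± 0.37), ONECUT2 (1.15 ± 0.23) and CEBPB (0.81 ± 0.24) against ESR1 (-1.99 ± 0.54). Adjusted over the list alone, 0 plasma protein and 0 urea cycle genes passed, 1 acute phase gene fell, 5 bile acid genes rose, 6 glycolysis genes rose and 6 fell, and 4 transcription factors rose and 2 fell. With the preset correlation camera gave adjusted p of 0.33 for plasma proteins, 0.53 for the urea cycle, 0.34 for acute phase, 0.18 for bile acids, 0.82 for glycolysis and 0.27 for transcription factors. The model with log2 total counts gave 0.011 for acute phase (down), 0.018 for bile acids (up), 0.00022 for glycolysis (down) and 0.037 for transcription factors (up). In that model 0 bile acid genes rose, while 0 glycolysis genes rose and 2 fell.

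The remaining lists held genes going both ways or few that passed. Of 20 phase II conjugation genes 2 rose and 3 fell (1 and 2 adjusted over the list alone), UGT2B4 (log2 fold change 1.80 ± 0.59) against NAT1 (-0.99 ± 0.25), NNMT (-1.69 ± 0.63) and GSTP1 (-1.34 ± 0.45). Of 16 gluconeogenesis genes PCK2 rose (log2 fold change 0.77 ± 0.28) and GCKR (-1.31 ± 0.33) and FBP1 (-1.30 ± 0.46) fell, of which 0 rose and 1 fell adjusted over the list alone. Of 22 fatty acid oxidation genes 2 rose and 2 fell, also adjusted over the list alone: HADHA (log2 fold change 0.87 ± 0.24) and HADH (0.71 ± 0.23) against ACSM3 (-1.36 ± 0.35) and ACADVL. Of 17 fatty acid synthesis genes 3 rose and 0 fell (2 and 0 adjusted over the list alone, 4 and 3 without the pair nearer to the other tissue), namely ACLY (log2 fold change 0.89 ± 0.27), ELOVL5 (0.88 ± 0.27) and ELOVL6 (0.90 ± 0.34). Of 15 liver Wnt targets 3 rose (1 adjusted over the list alone), namely RNF43 (log2 fold change 1.23 ± 0.31), GLUL and ZNRF3 (0.67 ± 0.26). Of 10 oncofetal genes 2 rose and 4 fell, also adjusted over the list alone: GPC3 and SPINK1 against IGF2, SALL4 (log2 fold change -2.34 ± 0.59), IGF2BP2 and EPCAM. Of 13 IGF axis genes 1 rose and 4 fell, also adjusted over the list alone: INSR (log2 fold change 0.56 ± 0.22) against SOCS2, IGF1R (-2.18 ± 0.57), IGFBP3 (-1.18 ± 0.36) and IGFALS. Of 21 fibroblast and matrix genes 5 fell and 0 rose, also adjusted over the list alone (4 and 2 without the pair nearer to the other tissue), DCN (log2 fold change -2.87 ± 0.60), MFAP4 (-3.67 ± 0.87) and PDGFRA (-2.80 ± 0.79) among them. ACADVL, EPCAM and IGFALS were named after their values were seen.

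For these lists the preset adjusted p of camera was 0.82 for phase II conjugation, 0.97 for gluconeogenesis, 0.62 for fatty acid oxidation, 0.23 for fatty acid synthesis, 0.56 for Wnt targets, 0.35 for oncofetal genes, 0.18 for the IGF axis and 0.12 for fibroblasts. For gluconeogenesis the median log2 fold change was 0.12, the mean -0.09 and the camera direction down, and for Wnt targets 0.02, -0.10 and up. For fatty acid oxidation the median was 0.13, while the mean paired difference of the score was -0.0065. The cancer-testis list had 1 tested member, MAGEA10 (log2 fold change -0.24 ± 0.44), and the red blood cell list 4, of which SLC4A1 fell (-1.69 ± 0.47), so neither had a list test.

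**Figure D3:**
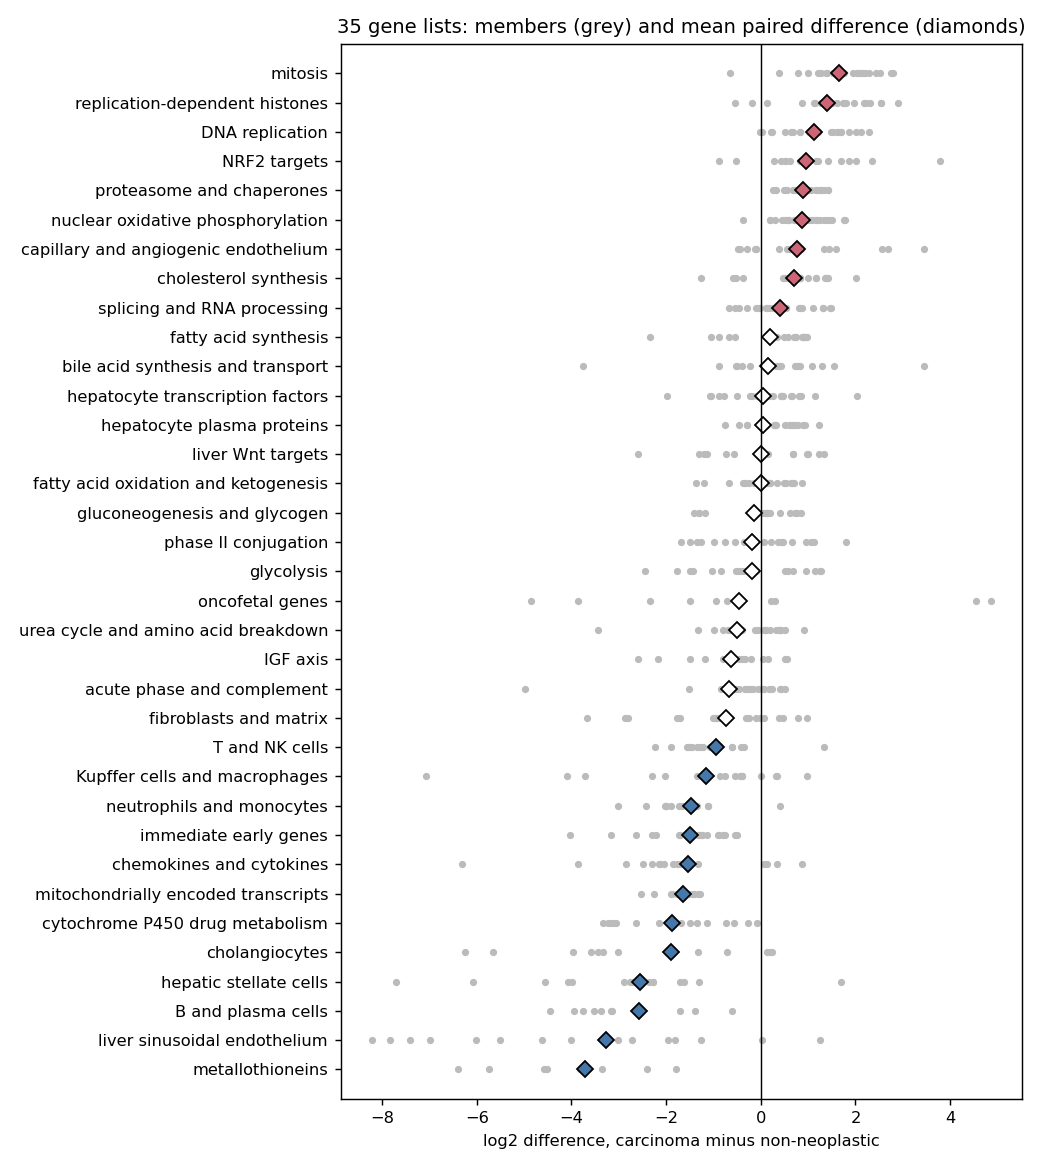
Each line is 1 of the 35 tested gene lists, with the fitted log2 fold changes of its members as grey points and the mean paired difference of the list score (carcinoma minus non-neoplastic, log2) over 17 pairs as a diamond. Red and blue diamonds mark the 9 lists called higher and the 12 called lower by camera with its preset correlation, of which 0 were called with an estimated correlation, and white diamonds were not called.

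Libraries of the tissues also differed in make-up. The 13 mitochondrially encoded genes took 3.77 ± 1.94% of the counts in carcinoma and 10.8 ± 7.81% in non-neoplastic libraries (mean ± SD, n = 17 each), and the carcinoma share was higher in 3 of the 17 pairs (two-sided permutation within patients, Benjamini-Hochberg adjusted p = 0.0081). The 100 most abundant genes took 31.7 ± 7.05% and 39.3 ± 7.95% (permutation, adjusted p = 0.021, higher in 6 pairs). Total counts were higher in the carcinoma library in 15 of the 17 pairs, with medians of 23911048 and 14950112 (permutation, adjusted p = 0.0081). The number of genes with at least 10 counts, 16008 ± 589 in carcinoma and 16502 ± 1663 in non-neoplastic libraries, did not pass the permutation test (adjusted p = 0.26, higher in 5 pairs). Counted from 1 count upwards, the number was lower in carcinoma (20522 against 22545, permutation adjusted p = 0.014).

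Over single genes, a difference in spread between the carcinomas and the non-neoplastic tissues was not found. The median over 16479 genes of the log2 ratio of the SD between carcinomas to the SD between non-neoplastic samples was -0.016 (two-sided permutation of tissue labels within patients, p = 0.95, 17 pairs), and 48.9% of the genes had the larger SD in carcinoma. Without the 3 pairs that held a library far from its own tissue, left out after seeing the data, the ratio was 0.29 (permutation p = 0.050). The scores of chromosome arms did vary more between carcinomas, with a mean log2 SD ratio of 1.02 over 39 arms (permutation p = 0.00021).

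In the main fit, genes on chromosome arms 8q and 1q had the highest medians and those on 8p and 17p the lowest of the 39 arms. The median log2 fold change was 0.48 over 337 genes of 8q and 0.37 over 721 genes of 1q, against -0.43 over 187 genes of 8p and -0.39 over 282 genes of 17p. With the trend on GC content and transcript length removed, 8p (-0.27) and 18p (-0.24) were lowest. Without the patient block 17p (-0.36) and 18p (-0.33) were. Of the 8q genes 40.9% were called higher and 11.9% lower, and of the 17p genes 3.90% and 31.6%. Camera with an estimated correlation called 0 of the 39 arms, with a lowest adjusted p of 0.97, and 0 arms had an unadjusted p under 0.05. A permutation of tissue labels within patients, chosen after seeing the data, called 12 arms. Of these, 8q (higher relative to all autosomal genes in 15 of 17 pairs, by 0.50 ± 0.51, mean ± SD, permutation adjusted p = 0.0041), 1q (15 pairs, 0.41 ± 0.35, adjusted p = 0.0053), 6p, 20p and 5q were higher. Lower were 17p (higher in 2 of 17 pairs, -0.36 ± 0.33, permutation adjusted p = 0.0041), 8p (4 pairs, -0.34 ± 0.39, adjusted p = 0.016), 12p, 6q, 19q, 21q and the set labelled 4p, which holds only the part of chromosome 4 before 31146806 (GRCh38) and not the whole short arm.

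**Figure D4:**
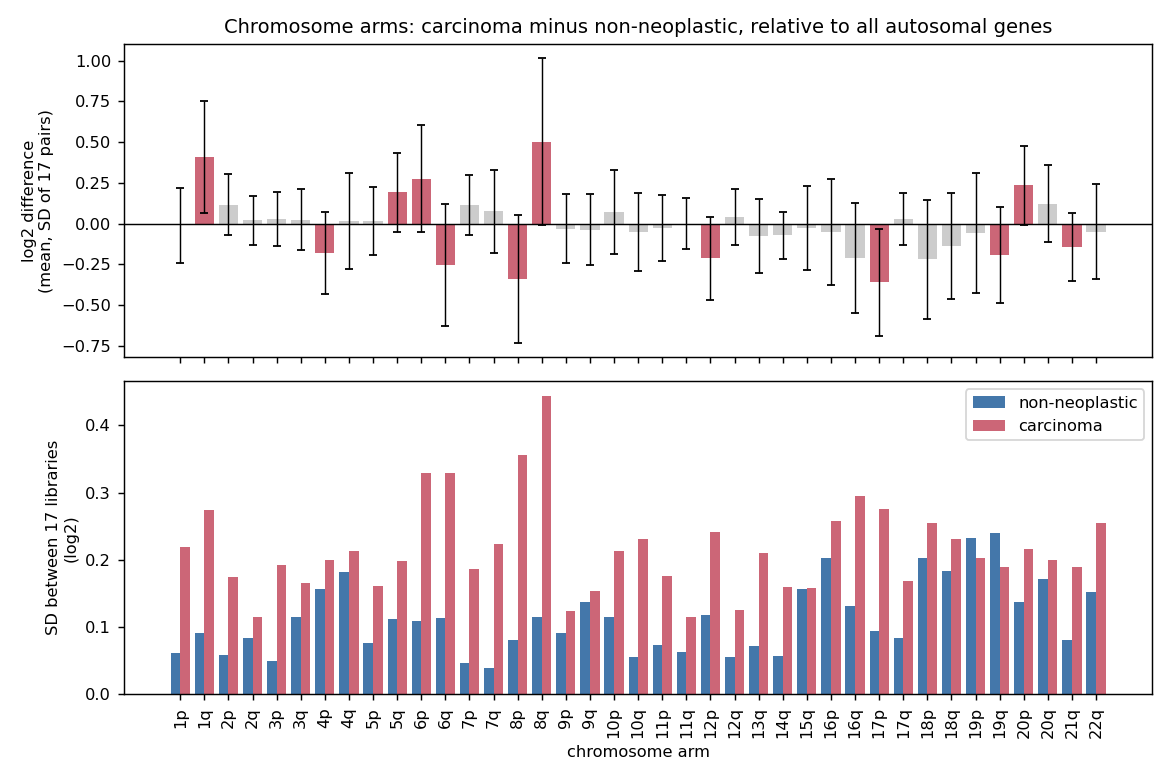
The upper plot gives, for each of 39 autosomal arms, the mean over 17 pairs of the median log2 difference (carcinoma minus non-neoplastic) of its genes relative to all autosomal genes, with the SD between pairs as error bars and, in red, the 12 arms with an adjusted p below 0.05 by permutation within patients. The lower plot gives the SD of the arm score between the 17 libraries of each tissue (log2), which was larger in carcinoma for 37 of the 39 arms, for 8q at 0.44 against 0.11.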

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

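The tests with total counts as a covariate, thinned libraries, pairs left out and permuted scores were chosen after seeing the data. Of 132 named genes with a test, 109 kept their side of the threshold in every fit read that was not chosen after seeing the data. Fits with each patient left out and the other thresholds were not read gene by gene. The stricter filter left some named genes untested, and these were not counted as changed. In the fits read, 0 named genes called in the main or the alternative fit changed direction. MAGEA10, not called in either, went from -0.24 to 0.70 (log2) with total counts as a covariate. Without the patient block, which pairs the samples, 3322 genes were higher and 3383 lower, 13 named genes lost their call, and the calls of all 35 lists stayed on their side. Leaving out each patient in turn gave 2700 to 3986 higher and 2539 to 3647 lower genes. At an adjusted p below 0.01, a stricter threshold by construction, 1762 were higher and 1634 lower, and against a fold change of 2, 59 and 443. With total counts as a covariate 75 were higher and 318 lower, and 375 of the 393 were also called without it. In that fit 104 of the 132 named genes lost their call, some with a fold about as large, such as AKR1B10 (3.78 and 4.13), CAP2 (2.30 and 2.12) and FOSB (-4.04 and -3.86). Others lost it with a smaller fold, such as H2BFS (3.07 and 0.75), HIST1H3B (2.54 and 0.95) and CDC20 (2.75 and 1.21). Upper-quartile factors moved the median of all genes from -0.06 to -0.18 (log2), and gave 2552 higher and 3906 lower genes. DESeq2 called 3794 and 4481 and limma-voom 3218 and 3466.

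With an estimated correlation camera called 0 lists higher and 0 lower. The adjusted p was then 0.303 for mitosis, DNA replication, replication-dependent histones, NRF2 targets, nuclear oxidative phosphorylation, metallothioneins, proteasome and chaperones, liver sinusoidal endothelium, hepatic stellate cells, B and plasma cells, neutrophils and monocytes, chemokines and cytokines and immediate early genes. It was 0.377 for cholesterol synthesis, mitochondrially encoded transcripts and cholangiocytes, 0.333 for T and NK cells, 0.342 for Kupffer cells and macrophages, 0.401 for cytochrome P450 drug metabolism, 0.412 for splicing and RNA processing and 0.581 for capillary and angiogenic endothelium.

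With total counts as a covariate the preset camera adjusted p passed the threshold for acute phase and complement (0.0108), bile acid synthesis and transport (0.0184), glycolysis (0.000221), hepatocyte transcription factors (0.0366), liver Wnt targets (0.0366), the IGF axis (0.0126) and fibroblasts and matrix (1.25e-07). It no longer did for cytochrome P450 drug metabolism (0.0528), NRF2 targets (0.0514), splicing and RNA processing (0.253) and capillary and angiogenic endothelium (0.865). Without the 3 pairs holding the shallowest libraries it was 0.00694 for hepatocyte plasma proteins, 0.00720 for bile acid synthesis and transport, 0.00112 for fibroblasts and matrix and 0.0703 for capillary and angiogenic endothelium. Without the pairs holding a library far from its tissue it was 0.0231 for fibroblasts and matrix. With thinned libraries it was 0.0581 for capillary and angiogenic endothelium and 0.0638 for cholangiocytes. Fry gave 0.00443 for oncofetal genes, 0.00556 for the IGF axis and 0.0878 for capillary and angiogenic endothelium, and permuted list scores gave 0.0432 for oncofetal genes and 0.00213 for the IGF axis. Counting genes with at least 1 count, carcinoma libraries had a difference of -2023 genes (adjusted p 0.0142). Permuted arm scores called 12 chromosome arms. For each of these changes the cause was not tested.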

Other observations

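The genes of the next paragraph, and the tests of thinning, of the respiratory chain and proteasome lists against total counts, and of the pair with both libraries nearer to the other tissue, were chosen after the result was seen, as were the permuted arm scores. The rule that reads the direction of genes in that pair was also set after its value was seen.

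Several genes outside the lists moved in every pair. KLHDC10 was higher in 17 of 17 pairs, from 44.9 ± 25.4 to 133.1 ± 62.5 CPM (log2 fold change 1.61 ± 0.17, edgeR adjusted p = 0.00012). UCHL5, a deubiquitinase that binds the proteasome, was also higher in 17 (log2 fold change 1.53 ± 0.18). NTRK3, a neurotrophin receptor gene, was lower in 17 of 17 pairs, from 11.7 ± 19.6 to 0.94 ± 0.95 CPM (log2 fold change -3.49 ± 0.42), as was the sodium-calcium exchanger gene SLC8A1 (log2 fold change -1.87 ± 0.22).

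Of 60 splits with tissue labels swapped within patients, the real one included, 1 called as many genes as the real labels. The real labels called 6410 and the highest other split 1, so chance can be excluded for the count of genes. For the count of lists called by camera with its preset correlation, 13 of the 60 splits called as many. The real labels called 21 lists, the median of the other splits was 17 and the highest 23, so chance cannot be excluded for that count. Permuted scores within patients passed for each of the 21 lists, at an adjusted p of 0.0014 for metallothioneins and at most 0.038, for the capillary list. That permutation asks only whether a score differs between the tissues. It does not compare a list with other genes, of which many changed too (38.9% of tested genes were called). It therefore does not show that a list moved more than other genes.

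Total counts were higher in carcinoma, and calls fell from 6410 to 393 with total counts in the model. The carcinoma library was the deeper one in 15 of 17 pairs, so depth and tissue cannot be fully separated. Lost calls alone do not show that depth is the cause. With every library thinned to the smallest total 5328 genes were called, and 4957 of the 6410 calls held. Fewer counts in the non-neoplastic libraries are thus argued against as the source of those calls. Only 14056 genes passed the filter there against 16479, so the lowest genes were not judged. The thinned fit did not include total counts, so it cannot tell why calls fell in the model that did. A library property that follows total counts within each tissue may contribute to the higher respiratory chain and proteasome scores. The within-tissue slope took off 0.54 of the 0.88 and 0.48 of the 0.90 (log2) mean paired difference. A property that total counts track only loosely would be taken off only in part. The lower bounds of the change left were 0.0689 and 0.16, which argues against the part that this slope captures as the whole cause. The same test left the mitosis list with a lower bound of 0.71 and the sinusoidal, stellate and metallothionein lists with upper bounds of -1.44 or lower. For the cholesterol (0.051, 95% bootstrap interval -0.62 to 0.55), NRF2 (0.62, -0.066 to 1.37) and capillary lists (0.54, -0.20 to 1.28) what was left included 0, and what makes scores follow total counts was not tested.

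In 1 of 17 pairs both libraries lay nearer to the other tissue, and in 2 further pairs 1 library did. Of the 717 genes that moved the same way in all other pairs 86.6% ran opposite there, while others, AURKA and IGF2 among them, ran as labelled. Such genes also place the libraries, so this share neither supports nor excludes exchanged tissue labels. A deeper non-neoplastic library cannot be judged either: only 2 pairs had one, and 1 of them had no majority of lists opposite. Exchanged labels, depth and a biological difference of both samples of that pair stay open. A difference of the carcinoma alone would not place the non-neoplastic library nearer to the other tissue, since each library was compared with other patients only.

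A candidate explanation for the higher medians of 1q and 8q is copy number gain in part of the carcinomas, offered as a hypothesis. The SD between libraries of these arm scores was larger in carcinoma, with a mean log2 ratio of 1.77 (permutation p = 3e-05). Over all 39 arms the mean log2 ratio was 1.02 (permutation p = 0.00021). GC content and transcript length are argued against, since the 1q median minus that of all autosomal genes was 0.42 before and 0.38 after that trend was removed, and that of 8q 0.53 and 0.50 (log2). DNA copy number was not measured in these data.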
